A study of Mus musculus with 2 samples.

How the data were processed

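Hearts of mouse embryos at embryonic day 13.5 were collected, total RNA was extracted and standard Illumina libraries were made, per the labels' protocols. The series holds 2 libraries, 1 wild type and 1 Srsf10 knockout, and each was placed in its group by the genotype in its labels. Alignment with Bowtie 0.12.2 and the mm9 genome are named in the submitters' processing notes. The annotation release, read filters and use of strand are not given in the sources used here. Each library had its own deposited gene table with Ensembl gene identifiers.

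The deposited counts are whole numbers of uniquely mapped reads per gene, per the file headers. They summed to 39.61 M reads in the wild-type library and 38.89 M in the knockout library, which equals the total each header states. The smallest listed count was 1, so a gene missing from a table was taken as 0 reads. The authors also deposited RPKM, reads scaled to the listed gene length in kilobases and to that total, and recomputing it from count, length and total gave the same values to a relative deviation of 2.1e-14. A deposited coverage column gives the share of each gene's listed length covered by reads, and it was used only for Srsf10. Since only uniquely mapped reads are counted, genes with near-identical copies are measured only through their distinct parts. The listed length differed between the tables for 76 genes, 5 of them expressed.

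The tables named 17646 genes, 17196 of which received a symbol from a table of gene names matched on Ensembl identifier. The values analysed were log2 ratios, knockout over wild type, of RPKM + 1, for 12329 genes with an RPKM of at least 1 in at least one library. A pseudocount of 1 understates the ratio of low genes. Fold values given with an interval are ratios of reads per library read without a pseudocount, with exact conditional binomial (Clopper-Pearson) 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. For a gene with 0 reads in a library, a bound was computed against a floor of 3 reads, which is 0.0757 reads per M reads in the wild-type library and 0.0771 in the knockout library. At RPKM 1 and the median gene length of 3130 bases, a gene had about 124 reads.

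No test across genes was run, because 1 library per group leaves no residual degrees of freedom, although the tables hold counts. Before the data were examined, the design had assumed RPKM values, and the analysis on log2(RPKM + 1) was kept. Genes were counted where they differed at least 2-fold, in each direction. Before the data were examined, 31 gene lists with 553 genes were fixed. They cover the sarcomere, calcium handling, ion channels, transcription factors and other cardiac programs, splicing factors, proliferation, stress and metabolism, matrix, markers of other cell types, imprinted genes, ribosomal proteins, histones and sex-linked genes. Of these genes 540 were listed, 6 of them under an older symbol. The median log2 ratio of each list's measured members was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart where its median lay outside the central 95%, and lists with fewer than 5 measured members, and the sex-linked list, were given as values only.

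The genes named were fixed by rule before the data were examined: Srsf10, and the 12 genes with the largest positive and the 12 with the largest negative log2 ratio among genes with an RPKM of at least 5 in one library. Predicted, clone-named, mitochondrial, pseudogene and sex-linked names were left out of these. For a list that stood apart, the 3 members with the largest ratio in its direction and its most abundant member were named. For any other list, the most abundant member and the member with the largest absolute log2 ratio were named. Trdn, Ryr2, Casq2, Atp2a2 and the sex-linked genes were added. Names chosen after their values were seen are said to be so where they appear.

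Chromosome, gene order and sequence similarity came from the GENCODE M21 annotation of GRCm38, since no mm9 annotation was used here, and no coordinates are given. For the longest transcript of each gene, the percent of 31-base words also present in another gene's transcripts was computed, and genes at 20% or more were taken as having a near-identical copy. This measure does not separate copies elsewhere in the genome from other genes annotated over the same place. Of the expressed genes, 98.8% had a transcript there. Overlapping and antisense genes cannot be told apart, as the use of strand is not given.

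Alternatives were pseudocounts of 0.1 and 5, no filter, an RPKM of at least 5, a mean RPKM of at least 10, rules of 1.5-fold and 3-fold, 3 rescalings of the RPKM and random lists not matched on expression. Alternatives added after the data were seen were a rescaling to reads outside the mitochondrial genes, leaving out near-identical copies and Y-linked genes, the wild-type gene length in both libraries, and centring on genes of like length or GC content in 10 bins. The procedure was tested on simulated counts drawn for the comparison of knockout with wild type, with 200 genes changed, 50 per size. Of 11987 unchanged genes 0 were called 2-fold. Of genes changed 2.5-fold 90% were called, of those changed 4-fold 100%, of those set to 0.4 of wild type 64.6% and of those changed 1.5-fold 0%. Among simulated random lists of 20 unchanged genes, 3.5% fell outside the central 95%. The exact interval held the true ratio for 95.3% of the unchanged simulated genes, so the simulated spread was that of counting. Spread beyond counting, such as that between embryos, is not in these shares, so they are not error rates of the genotype comparison. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.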

Results

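RNA from the heart of mouse embryos was sequenced at embryonic day 13.5, with 1 wild-type library and 1 Srsf10 knockout library, both on a BALB/c background. Srsf10 encodes a splicing factor of the SR protein family. The comparison asks which heart transcripts differ in level when Srsf10 is lost. The wild-type library held 39.61 M uniquely mapped reads over 16988 genes and the knockout library 38.89 M reads over 17068 genes. The labels do not give the number or the sex of the embryos behind each library. With 1 library per group, no difference has a replicate check and none was tested for significance. The 95% intervals given are exact intervals of read ratios and cover counting error only, so higher and lower refer to these 2 libraries.

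Srsf10 (ENSMUSG00000028676) was nearly lost from the knockout library. It had 5245 reads (35.3 RPKM) in the wild-type heart and 212 reads (1.45 RPKM) in the knockout heart, a level 24.3-fold lower (21.2 to 28.0), or 4.12% of wild type (3.57 to 4.72). The log2 ratio of RPKM + 1 was -3.89. The remaining reads were spread along the gene: 86.17% of its listed length was covered in the knockout and 90.04% in the wild type. A set of 198 genes with like read numbers and length had a median coverage of 86.47%. The gene lies on chromosome 4 in the GRCm38 annotation, and the listed length was 3754 bases.

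Expression in the hearts was otherwise close. Of 12329 genes with an RPKM of at least 1 in one library, 97.0% lay within 1.5-fold, and the median log2 ratio was -0.01 with quartiles of -0.14 and 0.13. Across genes, which are not replicates, Pearson's r of log2(RPKM + 1) was 0.987 and Spearman's rho 0.986. At least 2-fold differences were seen for 67 genes, 26 higher and 41 lower in the knockout library, and at least 1.5-fold differences for 187 higher and 177 lower. The 2-fold counts depend on the pseudocount: 109 higher and 100 lower with 0.1, and 6 and 17 with 5. Among the 67 genes, 4 were Y-linked and 22 shared at least 20% of their 31-base words with another annotated gene, so that uniquely mapped reads measure them with less certainty. Leaving out both kinds gave 17 genes higher and 24 lower. These counts keep 3 genes without a transcript in the annotation, whose shared words are unknown. Without these 3, 16 genes were higher and 22 lower. The largest ratios lay in pseudogenes that the naming rule leaves out, picked here after their values were seen. Gm10036 had 46 reads in the wild type and 4014 in the knockout, Gm10154 1615 and 2, and Gm10240 2484 and 14. They share 77.0%, 90.1% and 100% of their words with other genes.

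**Figure D1:**
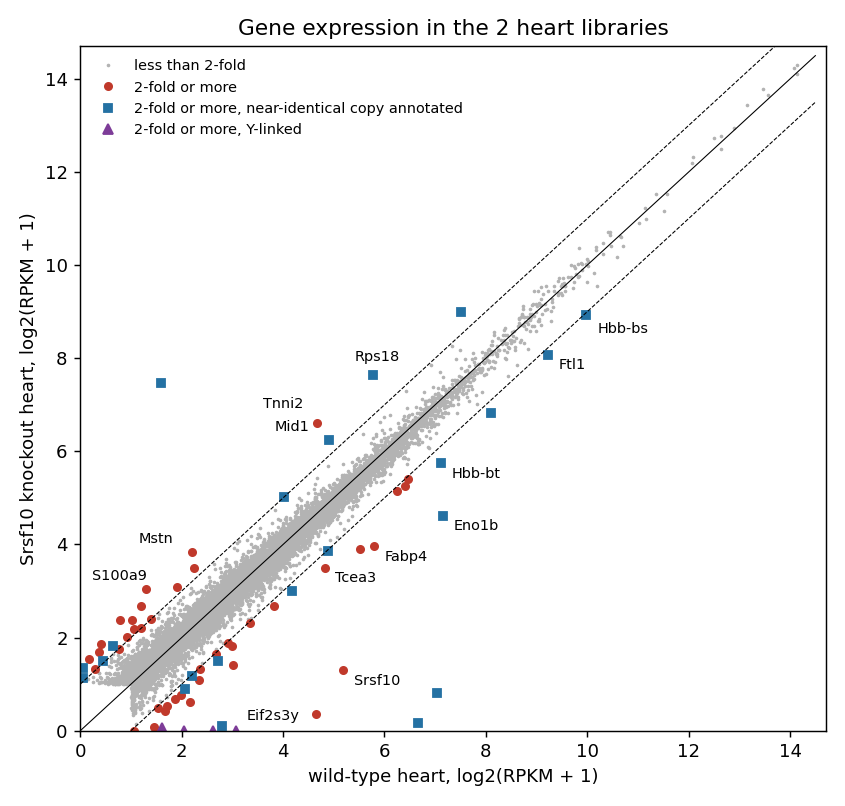
Expression of each gene in the wild-type heart (x axis) and the Srsf10 knockout heart (y axis), both as log2(RPKM + 1), with 1 library each; the solid line marks equal values and the dashed lines a 2-fold difference. Colours and shapes mark the 67 genes at least 2-fold apart, those with a near-identical annotated copy and those on the Y chromosome; Srsf10 lies far below the lines, at 35.3 RPKM against 1.45.

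Among the genes named by rule, Tnni2, S100a9, Mstn and Rps18 had the largest ratios in favour of the knockout heart. Tnni2, the fast skeletal troponin I, had 24.4 RPKM in the wild type and 96.8 in the knockout, 3.97-fold higher (3.68 to 4.28). Mstn, the muscle growth inhibitor myostatin, was 3.67-fold higher (3.28 to 4.12), and Car3, a carbonic anhydrase abundant in slow skeletal muscle and fat, 2.05-fold (1.83 to 2.30). Myl1, the light chain of fast skeletal and fetal muscle myosin, went from 119 to 229 RPKM, 1.92-fold higher, although 28.4% of its 31-base words occur in another gene. S100a9, a calcium-binding protein of neutrophils, was 4.99-fold higher (3.35 to 7.66) at only 30 and 147 reads, and Cd52, a leukocyte surface glycoprotein, 2.71-fold higher (1.98 to 3.75). Mid1, a ubiquitin ligase gene placed on the X chromosome in the annotation, was 2.60-fold higher (2.51 to 2.69), with 27.9% of its words shared. Cyp4f13, a cytochrome P450, was 2.74-fold higher, Adh6b, an alcohol dehydrogenase, 2.11-fold, and Sfi1, a centrin-binding protein, 2.04-fold. The ribosomal protein genes Rps18 (3.71-fold) and Rpl21 (1.90-fold) completed the 12 largest, with 38.1% and 27.4% of their words shared with other genes.

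At the other end, Fabp4, a fatty acid-binding protein of adipocytes, macrophages and capillary endothelium, had 54.6 RPKM in the wild type and 14.6 in the knockout, 3.74-fold lower (3.33 to 4.22). Tcea3, a transcription elongation factor of the TFIIS family, was 2.64-fold lower (2.38 to 2.93), and Adprhl1, an ADP-ribosylhydrolase-like gene of the heart, went from 83.3 to 37.2 RPKM, 2.24-fold lower (2.12 to 2.36). The matrix genes Col15a1 (basement membrane collagen XV) and Smoc2 (a secreted calcium-binding matricellular protein) were 2.78-fold and 2.45-fold lower. Fmc1, linked to assembly of the mitochondrial ATP synthase, was 2.16-fold lower, and Tsacc 4.25-fold lower at 169 and 39 reads. The other 5 of the 12 share much of their sequence with other genes: Eno1b (5.98-fold lower, 88.4% of words shared), Prnd (3.02-fold, 98.3%), Hbb-bt (2.63-fold, 59.4%), Hist3h2ba (2.43-fold, 37.2%) and Ftl1 (2.23-fold, 85.4%). Where such words lie in copies elsewhere in the genome, reads can be split differently between copies, so these single-gene values are uncertain. The measure does not separate such copies from genes annotated over the same place. Tcea3 and Col15a1, like Cd52 above, lie on chromosome 4, as Srsf10 does.

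The libraries also differed in sex-linked transcripts. Y-linked genes had 2955 reads in the wild-type library and 18 in the knockout. Ddx3y, Eif2s3y and Kdm5d had 937, 908 and 675 reads in the wild type and 0 in the knockout, at least 307-fold, 297-fold and 221-fold lower against a floor of 3 reads. Uty had 423 and 7 reads, 59.3-fold lower (28.5 to 148). The 420 X-linked genes had a median log2 ratio of 0.01 and the 11741 autosomal genes one of -0.01. The wild-type library thus held RNA of male tissue and the knockout library almost none, so sex went with genotype in every comparison given here. Xist and Tsix are not among the listed genes.

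Sarcomere genes were slightly lower in the knockout heart as a group. Of the 24 members measured, 18 had a log2 ratio below 0, and the list median was -0.16, at percentile 0.12 of 10000 random lists matched on expression. Among members with an RPKM of at least 5 it was -0.10 at percentile 4.50, which did not stand apart. Myom2, an M-band protein, was 3.41-fold lower (2.80 to 4.18) at low level. The ventricular light chain gene Myl3 was 1.33-fold lower (1.31 to 1.35), cardiac troponin T (Tnnt2) 1.28-fold (1.26 to 1.29) and cardiac actin (Actc1), the most abundant member, 1.10-fold. Fatty acid oxidation genes, with 14 of 17 below 0, had a median of -0.15 (percentile 1.32). The transporter Cd36, the enzyme Ech1 and the heart fatty acid-binding protein Fabp3 were 1.33-fold, 1.31-fold and 1.32-fold lower. Without genes that have near-identical copies, Fabp3 among them, the fatty acid oxidation median was -0.12 at percentile 5.75 and no longer stood apart. Nuclear-encoded oxidative phosphorylation genes lay at a median of -0.09 (percentile 6.22, 35 members), which did not stand apart. Cox8b was 1.43-fold lower and Atp5b, the most abundant member, 1.04-fold lower.

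Calcium handling genes did not move as a group: 14 of 26 members were above 0 and 12 below, with a median of 0.00 at percentile 78.1. Single members differed in both directions. Trdn, the triadin of the sarcoplasmic reticulum junction, was 1.24-fold higher (1.196 to 1.285), while Casq2, the cardiac calsequestrin that binds it, was 1.31-fold lower (1.26 to 1.35). The calcium release channel Ryr2 was 1.10-fold higher and the calcium pump Atp2a2 1.06-fold lower. Sln, the atrial pump regulator sarcolipin, was 2.01-fold lower (1.64 to 2.47), and the chaperone Calr 1.13-fold lower. These values are totals per gene and do not separate splice forms.

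The other cardiac lists did not stand apart. Ion channel and gap junction genes had a median of -0.06 and a mean of 0.02 over 14 members. Kcnd2, a potassium channel, was 1.58-fold higher and Gja1, connexin 43, 1.07-fold lower. Cardiac transcription factors had a median of -0.09 over 26 members. Gata5 was 1.41-fold higher and the muscle methyltransferase Smyd1 1.04-fold higher. The fetal and hypertrophic stress list had a median of -0.03, with atrial natriuretic peptide (Nppa) going from 1168 to 747 RPKM, 1.56-fold lower (1.54 to 1.59), and Myh7 within 1.01-fold, with a direction that turned under 2 rescalings. Medians of the atrial and ventricular lists were -0.10 (12 members) and -0.06 (10 members). Myl7 and Myl2, the atrial and ventricular regulatory light chains, were 1.05-fold and 1.03-fold lower. Among 36 splicing factors and SR protein kinases the median was -0.04 (percentile 49.3). Hnrnpa1 was 1.55-fold lower there, with 29.5% of its words shared with other genes.

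Extracellular matrix and fibroblast or cushion mesenchyme markers were lower in the knockout library. Of 22 members, 17 were below 0, 6 were at least 1.5-fold lower and 1 was at least 1.5-fold higher, and the median of -0.17 lay at percentile 0.24. Elastin (Eln) was 1.73-fold lower (1.67 to 1.78), collagen VI alpha 1 (Col6a1) 1.59-fold (1.52 to 1.66) and decorin (Dcn) 1.55-fold (1.49 to 1.61), whereas Sparc, the most abundant member, was 1.10-fold lower. The fibrillar collagen genes, picked here after their values were seen, were lower by similar ratios: Col1a1 went from 224 to 148 RPKM, Col1a2 from 171 to 112 and Col3a1 from 201 to 134. Against this direction, and also picked afterwards, Vcan went from 59.3 to 97.4 RPKM and Hapln1 from 18.4 to 27.7. These encode versican and its link protein, which form the hyaluronan-rich matrix of the embryonic heart. Epicardial markers were higher, with a median of 0.25 at percentile 99.98 and 7 of 10 members above 0. Aldh1a1, a retinaldehyde dehydrogenase, was 1.79-fold higher (1.45 to 2.22), and the mesothelial genes Upk1b, Msln and Upk3b were 1.31-fold, 1.26-fold and 1.22-fold higher.

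**Figure D2:**
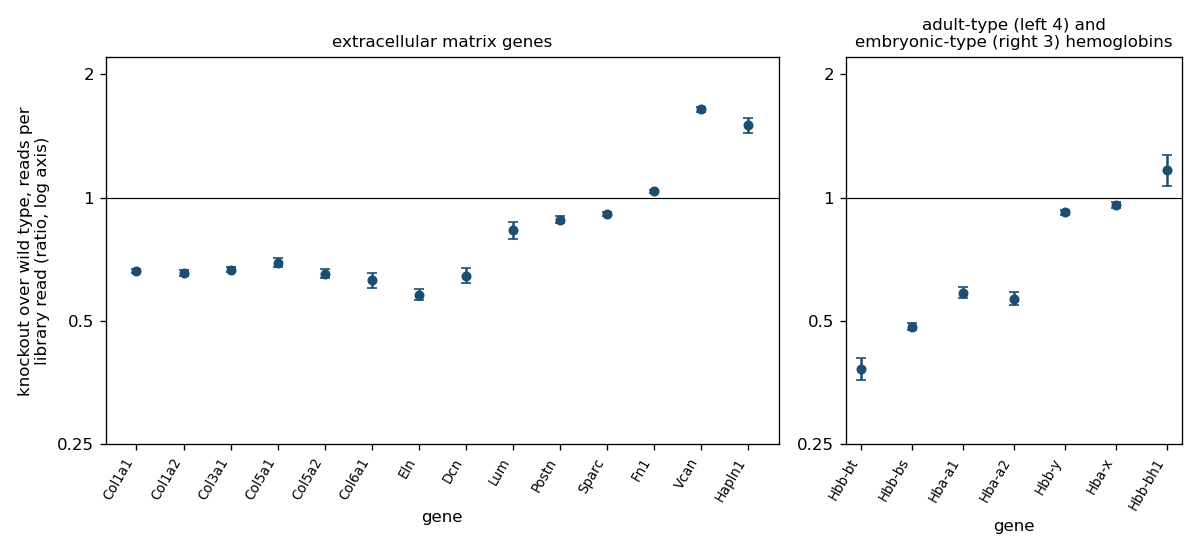
Ratio of reads per library read, knockout over wild type (y axis, log scale), for genes of the extracellular matrix (left, picked after the values were seen) and hemoglobin genes (right), with 1 library per genotype; bars are exact 95% intervals that cover counting error only. The collagen genes lie below 1 and Vcan and Hapln1 above it, and the 4 adult-type hemoglobins lie below the 3 embryonic-type ones.

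Adult-type hemoglobin genes were lower in the knockout heart, while other erythroid genes went both ways. Of 13 erythroid genes, 9 were below 0, with a median of -0.36 at percentile 0. The adult-type beta globin Hbb-bs went from 1012 to 489 RPKM, 2.07-fold lower (2.03 to 2.11), and Hbb-bt and the alpha globin Hba-a2 were 2.63-fold and 1.77-fold lower. The embryonic beta-like globin Hbb-y, the most abundant, went from 2077 to 1911 RPKM, 1.09-fold lower. The adult-type genes are near-identical copies, and without such genes the 9 remaining members had a median of -0.06 at percentile 31.5. When members below 1 RPKM were kept, the median was -0.09 at percentile 9.85, so the list stood apart in neither case. The erythroblast genes Klf1, Gata1, Rhag, Epb42 and Slc4a1, picked after the values were seen, were 1.11-fold higher (1.05 to 1.18) in summed reads. Summed over both copies, alpha globin reads were still 1.73-fold lower (1.69 to 1.77) and beta globin reads 2.12-fold lower (2.08 to 2.16). Hepatocyte markers were few (5 measured, median -0.11, not apart), but alpha-fetoprotein (Afp) had 145 reads in the wild type and 4 in the knockout, 35.6-fold lower (13.6 to 132), and albumin (Alb), picked after its values were seen, 88 and 0, at least 28.8-fold lower. Trf, transferrin, was 1.02-fold higher, with 80.7% of its words shared with other genes, and the 4 hepatocyte markers left without such genes had a median of -0.58. Hepatocyte markers went both ways, with 2 of the 5 measured above 0. When members below 1 RPKM were kept, the median of 13 members was -0.06 at percentile 4.8, which did not stand apart.

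Macrophage and leukocyte markers were higher in 12 of 14 members, with a median of 0.32 at percentile 100. The Fc receptor Fcgr3 was 1.92-fold higher (1.60 to 2.30), the lysosomal protein Cd68 1.64-fold (1.38 to 1.94) and lysozyme (Lyz2) 1.40-fold (1.29 to 1.53). Skeletal muscle markers were led by Tnni2, with Tnnt3 2.08-fold and Mylpf 1.33-fold higher, both parts of the fast skeletal sarcomere, but with muscle creatine kinase (Ckm) 1.36-fold lower. Their median was 0.33 at percentile 99.88 over 6 members. When members below 1 RPKM were kept as well, it became -0.01. Endothelial and endocardial markers (18 members, median -0.11, percentile 5.72) and smooth muscle markers (10 members, median 0.05) did not stand apart. In these lists, the junction gene Cldn5 was 1.80-fold lower, Eng (endoglin) 1.07-fold lower, Tagln (transgelin) 1.86-fold higher (1.80 to 1.93) and Myl9 1.13-fold higher. Neural crest, glial and neuronal markers had a median of 0.11 over 5 members, with Elavl4 1.42-fold higher and Erbb3 1.07-fold lower. Of the lung and foregut epithelial list only the keratins Krt8 (1.44-fold higher) and Krt18 (1.31-fold higher) were measured.

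The histone, imprinted gene, ribosomal protein and cell cycle lists lay higher in the knockout library, and each lost its call or turned under at least 1 other setting. Replication-dependent histone genes had a median of 0.37 (7 members, percentile 99.87), which became 0.17 at percentile 96.9 and no longer stood apart when members below 1 RPKM were kept. Hist1h2bc was 1.82-fold and Hist1h3c 2.10-fold higher, while Hist1h4d was 1.83-fold higher with an interval of 0.803 to 4.45. Imprinted genes had a median of 0.12 (12 members, percentile 99.52), which did not stand apart from random lists not matched on expression (percentile 97.3). Zim1, Peg3 and Mest were 1.53-fold, 1.27-fold and 1.18-fold higher, and the growth factor Igf2, the most abundant, was 1.22-fold lower. Cytosolic ribosomal protein genes had a median of 0.12 (25 members, percentile 99.98), with Rps18, Rps4x (1.21-fold), Rplp0 (1.19-fold) and Rpl32 (1.11-fold) all higher. Without genes that have near-identical copies, the 7 ribosomal protein genes left had a median of -0.04, so the direction turned. Cell cycle genes stood apart at percentile 98.2 with a median of only 0.02 and a mean of -0.02, which differ in sign. They did not stand apart from unmatched random lists (percentile 76.4), without near-identical copies (97.3), or after centring by gene length (96.7) or GC content (88.4). Mki67, a proliferation marker, went from 55.4 to 69.5 RPKM, and Ccne2 was 1.15-fold, Cenpe 1.13-fold and Pcna 1.04-fold higher.

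The stress lists and glycolysis did not stand apart. The list of p53 targets and apoptosis genes had a median of 0.07 over 15 members. Eda2r, an X-linked receptor of the TNF receptor family, was 2.23-fold higher (1.88 to 2.66) and cyclin G1 (Ccng1) 1.45-fold higher. The glycolysis median was 0.01 over 19 members, with Aldoa 1.02-fold lower and Eno1 1.62-fold higher. Eno1 shares 73.0% of its words with other genes, Eno1b among them. Medians were -0.04 for the hypoxia response (16 members), -0.04 for the unfolded protein and integrated stress response (14 members), -0.09 for immediate early and heat shock genes (11 members) and 0.08 for the interferon response (7 members). In these, Ankrd37 was 1.45-fold lower, Bnip3 1.03-fold lower, Atf3 1.41-fold lower and Hsp90b1 1.05-fold lower. Fos was 2.07-fold higher (1.65 to 2.62), Hspb1 1.57-fold lower with 56.7% of its words shared, Irf7 2.40-fold higher (1.66 to 3.53) and Bst2 1.29-fold higher. Of 29 lists with at least 5 measured members, 7 stood apart as higher, 4 as lower and 18 did not, where 1.45 would be outside by chance if genes were independent. The percentiles describe these libraries and do not test genotype, since the members of a list vary together.

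**Figure D3:**
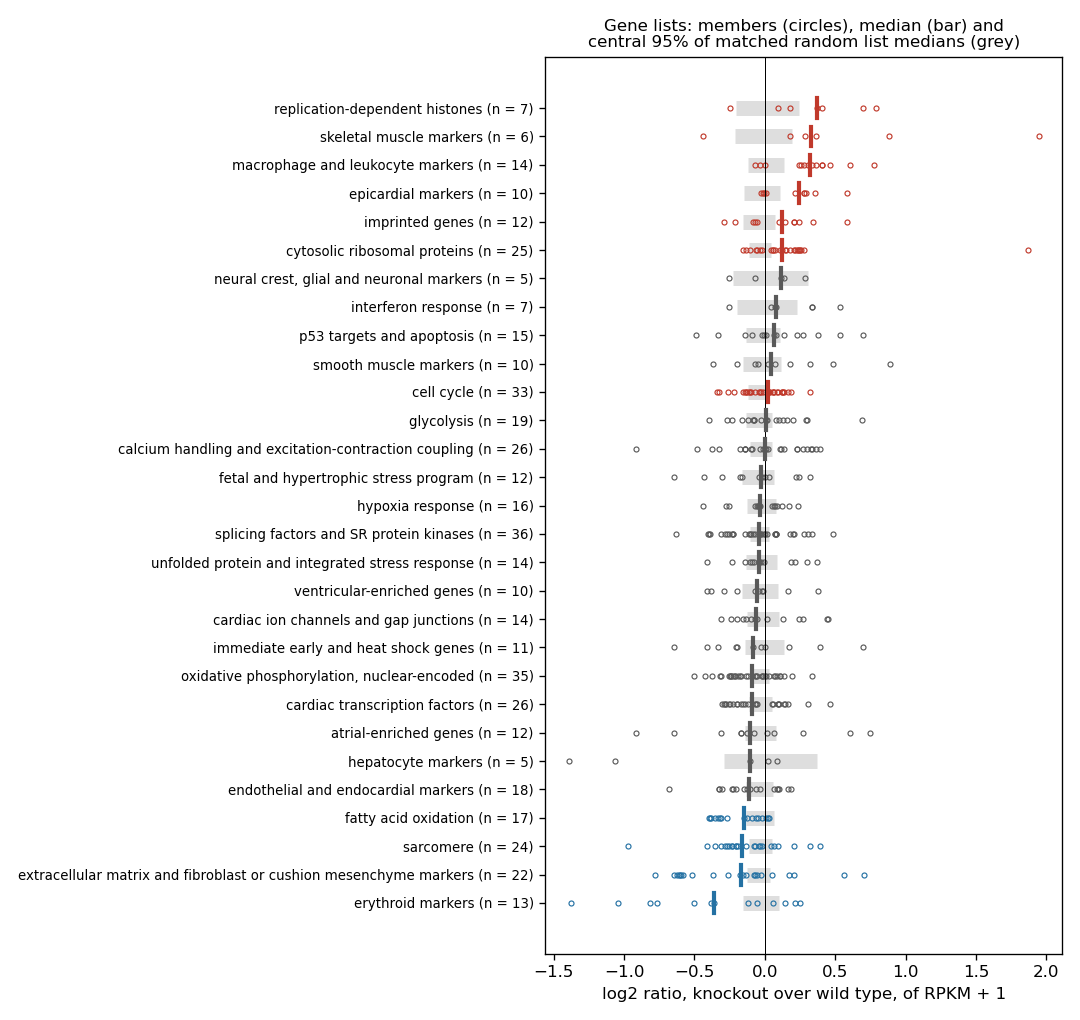
Log2 ratio of RPKM + 1, knockout over wild type (x axis), for the members of each gene list (circles), with the list median (bar) and the central 95% of medians of expression-matched random lists (grey), 1 library per genotype. The 7 lists above the grey range are led by replication-dependent histones and the 4 below it by erythroid markers.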

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

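The settings that leave out near-identical copies and Y-linked genes, rescale to reads outside the mitochondrial genes, use 1 gene length or centre by length or GC content were chosen after the data were seen. Against 26 genes at least 2-fold higher and 41 lower, a pseudocount of 0.1 gave 109 and 100, a pseudocount of 5 gave 6 and 17, an RPKM of at least 5 gave 11 and 27, a mean RPKM of at least 10 gave 6 and 17, the 1.5-fold rule 187 and 177, and the 3-fold rule 6 and 12. Without near-identical copies and Y-linked genes the counts were 17 and 24, with 3 genes that lack an annotated transcript kept. The counts follow from how far a pseudocount shrinks low genes, how many genes a filter keeps or where the fold threshold lies. Under each rescaling, whose shifts lay between -0.016 and 0.021 log2, the counts stayed within 1.5 times. The Srsf10 log2 ratio of -3.89 became -4.51 with a pseudocount of 0.1 and -2.64 with one of 5. Without a filter the skeletal muscle median turned to -0.012 and the erythroid (-0.088) and histone (0.17) medians no longer stood apart. With an RPKM of at least 5 the sarcomere median (-0.10) no longer stood apart. Against unmatched random lists, cell cycle (0.020) and imprinted genes (0.12) no longer did. Without near-identical copies the ribosomal protein median turned to -0.035, those of erythroid (-0.056), fatty acid oxidation (-0.12) and cell cycle genes (0.020) no longer stood apart, and 4 lists were apart as higher and 2 as lower. Centring by gene length (0.028) or by GC content (0.0012) also ended the cell cycle call. Lists that came to stand apart as lower were immediate early and heat shock genes without a filter (-0.13), oxidative phosphorylation against unmatched lists (-0.09) and cardiac transcription factors centred by length (-0.12). Beyond the members each setting removes, the cause was not tested. At an RPKM of at least 5, skeletal muscle markers and histones kept 4 and 2 members, and without copies hepatocyte markers and histones kept 4 and 3, too few for a percentile. Without a filter, Pearson's r was 0.993 and Spearman's rho 0.988, and with a pseudocount of 0.1, r was 0.980. Of 630 pairs of named gene and setting, 75 moved beyond the counting interval. This interval is wide for genes with few reads, so the count does not measure how stable the values are. Afp went from -1.39 to -0.42 with a pseudocount of 5 and was not counted as moved. In 2 of the 630 pairs the sign changed, both for Myh7 (-0.016). It became 0.0041 when rescaled without hemoglobin and the most abundant genes and 0.0018 when rescaled to reads outside the mitochondrial genes. No gene stood on several lines, so keeping every line gave no separate value. No paired analysis was possible because there was 1 library per group.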

Other observations

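All tests in this part, and all genes not already named above, were chosen after the results were seen. S100a8, Il18 and Alox5ap were higher in the knockout library. S100a8, the partner of S100a9 in neutrophil calprotectin, had 2 reads in the wild type and 29 in the knockout, 14.8-fold higher (3.74 to 128). The inflammatory cytokine gene Il18 was 2.80-fold higher (1.90 to 4.22) and Alox5ap, which is needed for leukotriene synthesis, 2.63-fold (1.91 to 3.66). Among secreted proteins, Sfrp2, a Wnt modulator, went from 87.6 to 41.6 RPKM, 2.10-fold lower (2.02 to 2.19). Igfbp6 and Igfbp3, which bind insulin-like growth factors, went from 2.97 to 0.694 RPKM and from 27.4 to 14.0 RPKM, and the elastic fibre gene Fbln5 was 1.88-fold lower (1.81 to 1.95), in the same direction as elastin. Has2, the hyaluronan synthase of the cardiac jelly, was 2.05-fold higher (1.84 to 2.29), in the same direction as Vcan and Hapln1.

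The atrial genes given here went both ways. Of the sinus node genes given here, for which no list was fixed, Shox2 differed most. Shox2, a transcription factor of the sinus node, was 2.30-fold lower (2.05 to 2.59) and the calcium sensor Vsnl1 2.05-fold lower (1.81 to 2.32), along with Sln and Nppa. The pacemaker channel Hcn4 was 1.13-fold lower (1.03 to 1.24) and Tbx3 1.19-fold lower (1.07 to 1.33), whereas Isl1 had a ratio of 1.15 with an interval of 0.955 to 1.40. Hcn4, Tbx3 and Isl1 thus lay within 1.5-fold, as did 97.0% of expressed genes. Bmp10, a member of the atrial list that is needed for growth of the embryonic myocardium, was 1.71-fold higher (1.59 to 1.83). In skeletal muscle genes, the higher Tnni2 and Tnnt3 were not joined by Myod1 and Myog, the regulators of the skeletal lineage, which had 18 and 41 reads in the wild type and 2 and 18 in the knockout.

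Adult-type globin transcripts (Hbb-bt, Hbb-bs, Hba-a1, Hba-a2) were lower by more than embryonic-type ones (Hbb-y, Hba-x, Hbb-bh1), with median log2 ratios of -0.93 and -0.06. Fewer blood cells in the knockout sample would lower both alike, but the medians differed by 0.875, more than the largest range within either set (0.608). An exchange of reads between listed copies would leave the sums equal, but even the alpha pair, which differed less, had a summed log2 ratio of -0.79. Only uniquely mapped reads are counted, so the sums cannot show reads that were lost from both copies. Fetal liver tissue in the wild-type sample stays open. The summed reads of 6 hepatocyte genes were 538 in the wild type and 308 in the knockout, and 313 and 82 without Trf. Trf shares most of its words with other annotated genes, and whether these are copies elsewhere or lie over the same place was not examined. However, 5 erythroblast genes, which such tissue would also bring, had a ratio of 1.11 (1.05 to 1.18). A lower share of definitive red cells with the genotype or a small difference in stage may also account for the lower adult-type globin transcripts. So may sex, which differed between the libraries by their Y-linked reads (2955 in the wild type and 18 in the knockout). These were not tested.

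Genes with near-identical copies were frequent among the 2-fold differences: of 64 such genes with an annotated transcript, 22 (34.4%) shared at least 20% of their words with another gene, against 3.13% to 17.2% in expression-matched random sets and 7.28% of all expressed genes. All of these shares also count genes whose words are shared with a gene annotated over the same place. Eno1b and Eno1 reads together came to 24079 and 24222, a ratio of 1.02 (1.01 to 1.04), although Eno1b alone was 5.98-fold lower. Ftl1 and its copy Ftl1-ps1 together gave a ratio of 0.978 (0.962 to 0.994). The adult-type globin pairs did not even out in this way: summed reads stayed 2.12-fold lower for beta and 1.73-fold lower for alpha. Sums for other genes with copies were not computed. For Eno1b and Ftl1, a candidate explanation is that reads were assigned differently between copies, as a sequence variant between the embryos' genomes would do. Variants were not examined, and a real difference in single genes stays open.

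Whether genes near Srsf10 on chromosome 4 differed more often than elsewhere was not settled. Among its 100 nearest expressed genes in the GRCm38 order, 7% differed at least 1.5-fold (Hmgn2, Cd52, Grrp1, Aunip, Tcea3, Cda and Nbl1), against a median of 3% over 10160 windows, at percentile 96.9. With 200 neighbours the share was 6.5% (percentile 98.5), with 50 it was 6% (88.1) and with 20 it was 0% (29.2), while 3% of the 100 nearest differed at least 2-fold (98.2). Outside the 100 nearest, Gm10154, Cort, Col15a1, Gm572, Dcdc2b and Tmem88b were also on chromosome 4 and at least 2-fold apart. No share of 2-fold genes per chromosome was computed. A chromosome segment that came with the targeted locus and differs from the wild-type one could give such a pattern. The share lay above the central 95% of windows only with 200 neighbours, where the upper limit was 5.5%. With 100 it lay at the upper limit under both fold rules. With 50 and 20 it lay inside the ranges, which were 0% to 10% and 0% to 15%. Such wide ranges leave little room to show an excess, so the narrow windows do not decide the question. An effect of Srsf10 loss on these genes cannot be told apart from such a segment, because both go with the genotype.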
